A study of Mus musculus with 12 samples.

How the data were processed

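Total RNA from mouse liver (C57Bl6) was measured on 12 Affymetrix MoGene 1.0 ST arrays. Per the labels, RNA was extracted with the Qiagen microRNEasy kit, amplified with the Nugen Pico WT system and labelled with biotin. Groups were taken from the labels alone: 3 libraries of sorted YFP-positive cells called uninduced hepatocytes, 3 of wild-type organoids, 3 of organoids with Yap on for 3 weeks in the liver and off for 2 weeks in culture, and 3 with Yap on throughout. The deposited values are intensities that the authors, per the submitters' processing notes, made with RMA, which subtracts background, applies quantile normalization and summarizes probes. No version or software was given. RMA returns log2 values, whereas the deposited intensities lie on a linear scale, so they appear to have been transformed back, and log2 was taken here. Detection calls, scan dates and slide numbers were not used here, and the genome build was not given in the sources used here, so that no coordinates are reported.

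Of 34760 array rows, 22961 were in the probe table, and 11799 that were not were left out. Rows naming several genes (1321) were left out too, and 21640 naming 1 gene were kept. For 954 genes with several rows, the row with the highest mean was used, leaving 19937 genes. A match of 21553 rows to RefSeq gene names changed 0 symbols, and 87 rows had no match. No filter on low values was applied. No 2 arrays were identical.

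Log2 values of all 12 arrays were fitted with group means in limma 3.58.1 (lmFit and eBayes, R 4.3.3), with 8 residual and 1.76 prior degrees of freedom, for 6 comparisons. All adjusted p-values of genes are from limma's moderated t-test with Benjamini-Hochberg adjustment over 19937 genes, called under 0.05. Standard errors are limma's and use the spread of all 4 groups. With 3 arrays against 3, a permutation test cannot give a two-sided p below 0.1, so none was used. The number of arrays limits the precision. Gene lists written before the data were examined were tested with camera in limma, 32 lists per comparison, with a preset correlation of 0.01 and adjustment over the lists, and again with the correlation estimated from each list. A list of sex-linked genes was described without a test. Medians of lists are of log2 fold changes. Genes are counted as without overlap when every array of 1 group lies above every array of the other. Figures were drawn with matplotlib 3.10.9.

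Genes were named by a rule fixed before the files were opened. It takes Yap1 and, for the 3 comparisons between organoid groups, the 10 called genes each way with the largest log2 fold change and no overlap. For the 3 comparisons against the libraries labelled hepatocyte it takes up to 10 each way called in the same direction in all 3 without overlap, ranked by the smallest change. Sex-linked genes and clone, predicted or multigene symbols were left out of these. It adds up to 4 members of each list with the largest change, passed or not, and all members of the YAP/TEAD and sex-linked lists.

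The fit was tested on simulated data with 100 changed genes per fold size, each group with its own spread and genes independent. At a log2 difference of 1 it recovered 48% of changed genes for Yap-on against Yap-off organoids, 42% for Yap-off and 50% for Yap-on against wild-type organoids, 58% for wild-type organoids against hepatocytes, and 45% and 42% for Yap-off and Yap-on organoids against hepatocytes. At a log2 difference of 2 these shares were 79%, 76%, 74%, 85%, 77% and 82%. In the same order, 4.76%, 53.6%, 41.6%, 65.8%, 26.9% and 29.8% of calls were false. The fit assumes 1 spread for all groups, whereas the simulated groups, like the libraries labelled hepatocyte and wild-type organoid, differ in spread. On 6 arrays the false shares were 13.6%, 19.4%, 29.9%, 14.3%, 14.5% and 28.3%. Overlaps of calls between comparisons were set against independent lists of the same sizes and beside 20 simulations of unchanged groups with shared controls.

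The alternatives were renewed quantile normalization, arrays centred on their median, the mean of a gene's rows or its most variable row, leaving out the 30% of genes with the lowest mean, only the 6 arrays compared, an intensity trend with robust eBayes, array weights, the replicate number as a block, a 2-fold minimum, adjusted p under 0.01 and leaving out each library in turn. A library was left out in turn only for the comparisons that include its group. After seeing the data, fits without the libraries labelled hepatocyte 2 and wild-type organoid 2 and a count without X- and Y-linked genes were added. The groups of the comparisons were never redrawn from the values. A split of the libraries labelled hepatocyte and wild-type organoid, picked from the grouping seen, served only to weigh an exchange of labels.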

Results

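Sorted liver cells and liver organoids from C57Bl6 mice were profiled on 12 Affymetrix MoGene 1.0 ST arrays, in 4 groups of 3 libraries. According to the labels, 1 group held YFP-positive liver cells sorted by FACS from uninduced animals and called hepatocytes, and 1 group held wild-type organoids. In the other groups, Yap, the transcriptional coactivator at the end of the Hippo pathway, had been switched on in the liver for 3 weeks before organoids were grown for 2 weeks. Doxycycline was absent from the culture of 1 of these groups, so that Yap was off (Yap-off organoids), and present in the other, so that Yap stayed on (Yap-on organoids). The median deposited intensity per array lay between 13.6 and 15.6 on a linear scale, and the highest between 7908 and 9588. The labels do not say whether replicates came from separate animals, so all p-values measure only the spread between these libraries, which may be technical.

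The libraries labelled hepatocyte and wild-type organoid did not group by label. Macrophage and endothelial transcripts were abundant in the library labelled hepatocyte 2 and in the libraries labelled wild-type organoid 1 and 3. Lyz2, a lysozyme of macrophages, stood at 12.04 (log2 intensity) in the library labelled hepatocyte 2 and at 11.56 and 12.16 in those labelled wild-type organoid 1 and 3. It stood at 5.28 and 6.30 in the libraries labelled hepatocyte 1 and 3 and at 6.19 in that labelled wild-type organoid 2. Cyp2e1, a cytochrome P450 of mature hepatocytes, followed the same split, at 10.14, 10.03 and 9.90 against 3.16, 3.22 and 2.74. Krt19, a keratin of bile duct cells, and Ankrd1, a YAP target gene, took the opposite one. Krt19 stood at 10.21, 9.82 and 9.28 in the libraries labelled hepatocyte 1, hepatocyte 3 and wild-type organoid 2, against 4.95, 4.28 and 4.92 in the others of these groups. For Ankrd1 the values were 10.40, 10.07 and 10.19 against 3.46, 3.39 and 3.47.

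Correlations across genes, which are not independent replicates, showed the same arrangement. Within groups r ranged from 0.992 to 0.995 for the Yap-on and from 0.975 to 0.983 for the Yap-off organoids, but from 0.822 to 0.989 for the libraries labelled hepatocyte and from 0.800 to 0.970 for those labelled wild-type organoid. The library closest to that labelled hepatocyte 2 was the one labelled wild-type organoid 3 (r = 0.951), and the library closest to that labelled wild-type organoid 2 was the one labelled hepatocyte 3 (r = 0.955). The labels were kept in every comparison, and each count against these groups is also given without the libraries labelled hepatocyte 2 and wild-type organoid 2, an alternative chosen after seeing the data. These 2 are called doubtful below because they differ from the rest of their groups, which does not tell whose labels are wrong. The libraries kept may be those whose profiles conflict with their labels. Those labelled hepatocyte 1 and 3 had high Krt19 and Ankrd1, and those labelled wild-type organoid 1 and 3 had high Cyp2e1 and macrophage transcripts. The comparison of Yap-on with Yap-off organoids takes no mean from the libraries labelled hepatocyte and wild-type organoid, although they enter its estimate of spread.

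**Figure D1:**
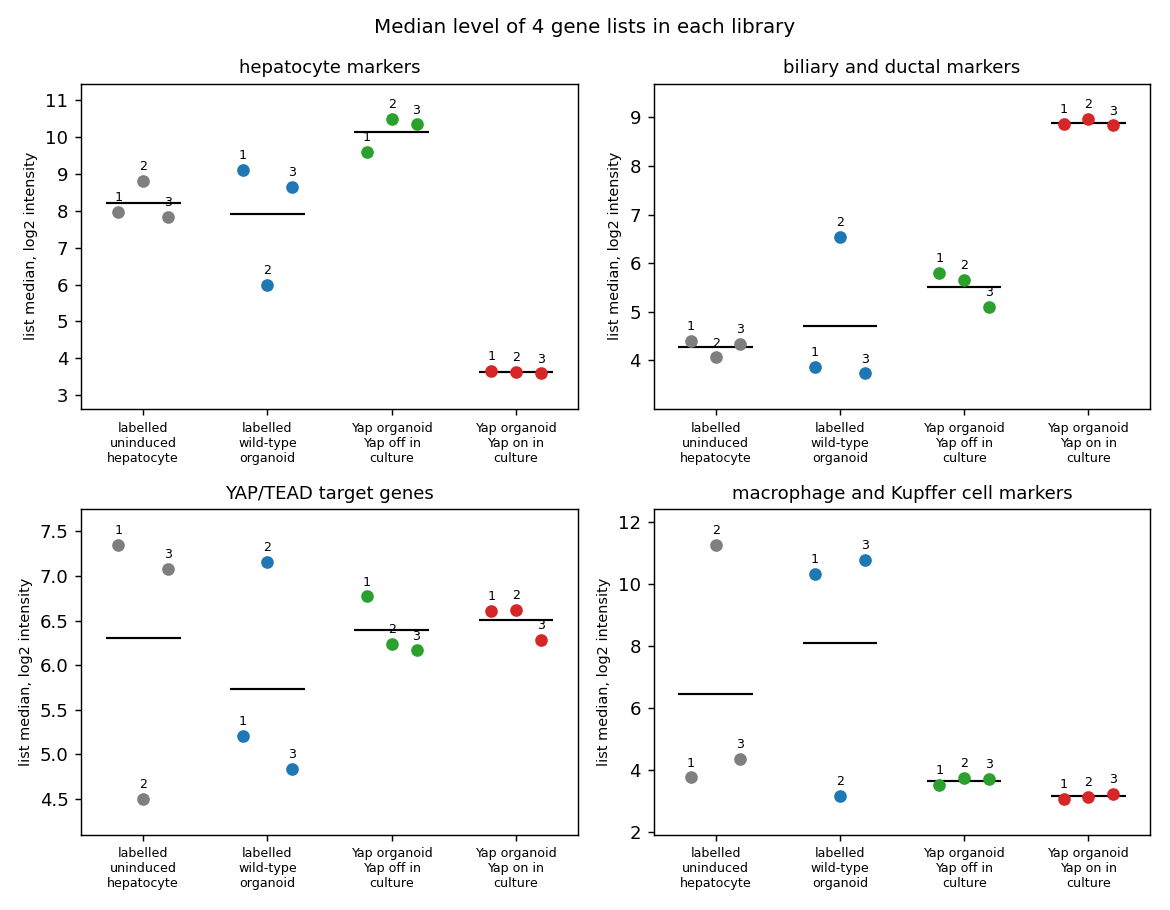
Median log2 intensity of 4 gene lists (panels, vertical axis) in each of the 12 libraries, by labelled group (horizontal axis); points carry the replicate number and lines mark group means. The hepatocyte list lies between 3.59 and 3.67 in the Yap-on organoids and between 9.59 and 10.49 in the Yap-off organoids, and the macrophage list is at 11.25 in the library labelled hepatocyte 2 against 3.76 and 4.34 in those labelled hepatocyte 1 and 3.

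The comparison of Yap-on with Yap-off organoids asks what keeping Yap on in culture does to organoids that began with Yap on in the liver. Transcripts of hepatocyte function were far lower with Yap on, while those of biliary and ductal epithelium were higher. Albumin (Alb) averaged 3.42 ± 0.22 (log2 intensity, SD, n = 3) in the Yap-on and 12.41 ± 0.14 in the Yap-off organoids, a log2 difference of -8.98 (SE 0.20, adjusted p = 5e-09). S100a14, an epithelial S100 protein, rose by 7.93 (SE 0.12, adjusted p = 5.3e-10), and the matrix protease Mmp7, a marker of injured and ductal epithelium, by 6.88 (SE 0.87, adjusted p = 0.00079). limma called 2283 of 19937 genes, 1413 higher and 870 lower with Yap on, and 974 and 571 of them differed at least 2-fold.

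The 10 largest increases among called genes without overlap between the groups were in S100a14, Aspa, Ctse, Anxa1, Prap1, Tmem54, Mmp7, Adgrg7, Gabrp and Rab25. Their log2 differences ran from 6.22 for Rab25 to 7.93 for S100a14. Several are known from digestive epithelium, among them the gastric protease cathepsin E (Ctse, 7.27 ± 0.31 SE) and Prap1, an intestinal secreted protein (7.01 ± 0.22). Rab25 acts in transport to the apical membrane of epithelia. In the Yap-off organoids S100a14, Aspa, Tmem54, Adgrg7, Anxa1 and Gabrp averaged from 2.89 (Aspa) to 3.48 (Gabrp), near the background of the array, so the size and order of these increases are limited by it. Ctse, Rab25 and Prap1 averaged 3.79, 3.86 and 3.98 there, below the array medians of 4.16 to 4.28, so background may limit their increases too. The 10 largest decreases were in Ahsg, Trf, Alb, Hp, Fgg, Serpina1c, Fga, Afp, Kng1 and Apoc3. They ran from -9.46 for the plasma protein fetuin (Ahsg) to -8.71 for the apolipoprotein Apoc3. All but Afp, the fetal albumin, encode plasma proteins of the adult liver, and Afp fell by 8.77 (SE 2.32, adjusted p = 0.037). The call for Afp was lost in each of the 6 fits without 1 of the Yap-on or Yap-off libraries, with adjusted p between 0.0785 and 0.109. It was also lost with the replicate number as a block (adjusted p = 0.085). The log2 difference stayed between -8.89 and -8.70 in the 6 fits. Its SE carries the spread of the libraries labelled hepatocyte and wild-type organoid, and the call held on the 6 arrays compared. In the Yap-on organoids these 10 genes lay between 2.43 (Serpina1c) and 3.68 (Alb), the level at which Y-linked genes stood in libraries with high Xist, so the decreases are limited by background as well.

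**Figure D2:**
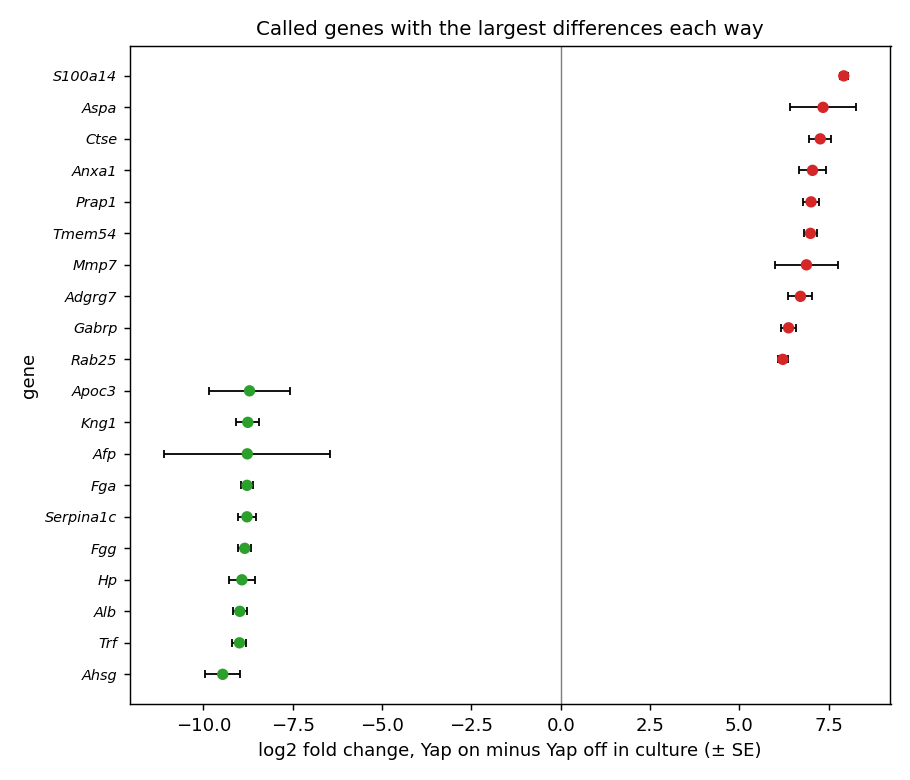
Log2 fold change, Yap-on minus Yap-off organoids (horizontal axis), of the 10 called genes with the largest differences each way (vertical axis); points are limma estimates and bars ± SE. The increases run from 6.22 for Rab25 to 7.93 for S100a14, and the decreases from -8.71 for Apoc3 to -9.46 for Ahsg, with the widest bar for Afp.

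Genes of liver function fell together. Of 29 measured hepatocyte markers, 21 fell and none rose (24 fell when adjusted over the list alone), with a list median of -4.20 (camera adjusted p = 2.6e-21; adjusted p = 0.032 with an estimated correlation). Complement and coagulation factors, which the liver secretes, fell for 25 of 29 members (27 adjusted over the list alone; median -4.52, adjusted p = 3e-27; adjusted p = 0.033 with an estimated correlation). Fgg, Fga and Fgb, the fibrinogen chains, differed by -8.84, -8.78 and -8.67. On all 12 arrays these were the only 2 of the 14 lists called that held with an estimated correlation, but which lists held depended on the arrays fitted. On the 6 arrays compared the biliary and the drug metabolism lists held (both adjusted p = 0.042), and the hepatocyte and the complement and coagulation lists did not (both 0.15). When the 2 doubtful libraries were left out, the hepatocyte (0.034), biliary (0.0074), drug metabolism (0.0074) and bile acid lists (0.046) held, and complement and coagulation did not (0.054). Genes of the urea cycle and amino acid breakdown fell for 21 of 23 members, the same number adjusted over the list alone (median -4.07, adjusted p = 5e-15; adjusted p = 0.0953 with an estimated correlation). Cps1, the entry enzyme of the urea cycle, differed by -8.24, and Tdo2, Tat and Mat1a by -7.81, -7.69 and -7.49.

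Drug and bile acid metabolism were lower as well. Of 22 drug metabolism genes 11 fell and none rose, over all genes and adjusted over the list alone (median -2.32, adjusted p = 1.2e-06; adjusted p = 0.056 with an estimated correlation). Cyp3a11, Cyp1a2, Cyp3a25 and Cyp2c29 differed by -6.81, -6.69, -5.56 and -5.42. Of 20 genes of bile acid synthesis and transport 10 fell and none rose, again also adjusted over the list alone (median -1.58, adjusted p = 9.6e-06; adjusted p = 0.056 with an estimated correlation). Among them were Abcc2, an exporter of the canalicular membrane (-6.47), Slc27a5 (-4.82) and Akr1d1 (-4.15). In the list of the unfolded protein response 9 of 20 members fell (11 adjusted over the list alone; median -0.76, adjusted p = 3.4e-05; adjusted p = 0.13 with an estimated correlation). They included Xbp1, a regulator of secretory capacity (-1.13), and the protein disulfide isomerases Pdia4 (-1.10) and Pdia6 (-1.05). Of 16 fatty acid synthesis genes 4 fell and 1 rose (5 and 1 adjusted over the list alone), and the list did not pass (median -0.61, adjusted p = 0.0876), although it was called lower on the 6 arrays (adjusted p = 0.048; adjusted p = 0.41 with an estimated correlation) and without the 2 doubtful libraries (adjusted p = 0.039; adjusted p = 0.21 with an estimated correlation). Its members that fell included Fads1 (-2.48), the transcription factor Mlxipl (-2.47) and Dgat2 (-2.40).

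Biliary and epithelial genes moved the other way. Of 24 biliary and ductal markers 8 rose and none fell (11 rose and 1 fell adjusted over the list alone), with a median of 2.27 (adjusted p = 1.9e-07; adjusted p = 0.29 with an estimated correlation). Muc1, a mucin of ductal surfaces, and Prom1, a progenitor and duct marker, rose by 6.17 ± 0.41 (SE) and 6.12 ± 0.27. Krt19 averaged 12.13 ± 0.12 (SD) in the Yap-on and 7.25 ± 0.29 in the Yap-off libraries, but its difference of 4.88 (SE 1.49) did not pass (adjusted p = 0.064), the spread being estimated over all 12 arrays. On the 6 arrays it passed (adjusted p = 2.3e-06). Of 20 genes of basement membrane and epithelial adhesion 5 rose and 1 fell, also adjusted over the list alone (median 1.01, adjusted p = 0.018; adjusted p = 0.86 with an estimated correlation). The laminin chain Lamb3 (3.74) and the integrins Itga6 (2.60) and Itga2 (2.59) rose, and nidogen (Nid1) fell by 4.40. This call ended when genes of low intensity were left out (adjusted p = 0.14). Of 21 gastrointestinal markers 3 rose and 1 fell, also adjusted over the list alone (median 0.11, adjusted p = 0.37). Lgals4 rose by 5.91 and Tff3 fell by 3.17, while Pdx1, a regulator of duodenum and pancreas, rose by 2.25 (SE 0.16, adjusted p = 1.4e-05).

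Genes of glycolysis and the hypoxia response were higher with Yap on. Of 21 members 4 rose and none fell (8 rose adjusted over the list alone; median 1.27, adjusted p = 6.6e-06; adjusted p = 0.54 with an estimated correlation). The carbonic anhydrase Car9 rose by 5.57 and Ankrd37 by 3.18. No member of the DNA replication and mitosis list passed singly, over all genes or adjusted over the list alone, but the 27 genes had a median of 0.81 (adjusted p = 0.0035; adjusted p = 0.86 with an estimated correlation). Mki67, the proliferation marker, differed by 1.23 (SE 0.51, adjusted p = 0.16). On the 6 arrays 9 members rose, Mki67 among them (adjusted p = 0.022), and 1 fell. This list call ended without the library labelled Yap-on 3 (adjusted p = 0.0729) and when genes of low intensity were left out (adjusted p = 0.0674). The fetal liver list had 6 members lower and 2 higher of 17 (7 and 2 adjusted over the list alone; median -1.11, adjusted p = 0.032; adjusted p = 0.54 with an estimated correlation). The imprinted growth factor Igf2 fell by 5.42, and the call ended without the library labelled Yap-off 3 (adjusted p = 0.0579).

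The gene whose expression was manipulated differed little. Yap1 averaged 7.38 ± 0.08 (log2, SD, n = 3) in the Yap-on and 7.15 ± 0.24 in the Yap-off organoids, a difference of 0.23 (SE 0.56, adjusted p = 0.83). Fitted on the 6 arrays of this comparison alone, the SE was 0.14 and the 95% interval ran from -0.10 to 0.57 (adjusted p = 0.24). It is not given in the sources used here whether the transgene is a sequence that the mouse Yap1 probes detect. Of 22 YAP/TEAD target genes 1 rose and 1 fell (0 and 1 adjusted over the list alone). The list median was 0.15 and its mean -0.10, and its camera test, which leaned upward, did not pass (adjusted p = 0.91). Axl, a receptor tyrosine kinase, fell by 2.71 (SE 0.48, adjusted p = 0.0057), and Dock5 rose by 0.97 at the edge of the threshold (adjusted p = 0.04999). Ankrd1 differed by -1.26 (SE 2.05) and Ccn2 by 0.77 (SE 1.45), neither passing. In the fit on 6 arrays, however, 14 of the 22 members were called, 7 higher and 7 lower, while the test of the list, whose members went both ways, did not pass (adjusted p = 0.87). Ankrd1 fell and Ccn2 rose there (adjusted p = 0.0070 and 0.0077). No member of the Hippo pathway list passed, over all genes or adjusted over the list alone (21 measured, median 0.13, adjusted p = 0.37). On the 6 arrays 5 of its members rose and 3 fell, and without the 2 doubtful libraries 4 rose, with the list uncalled in both fits (adjusted p = 0.41 and 0.33).

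**Figure D3:**
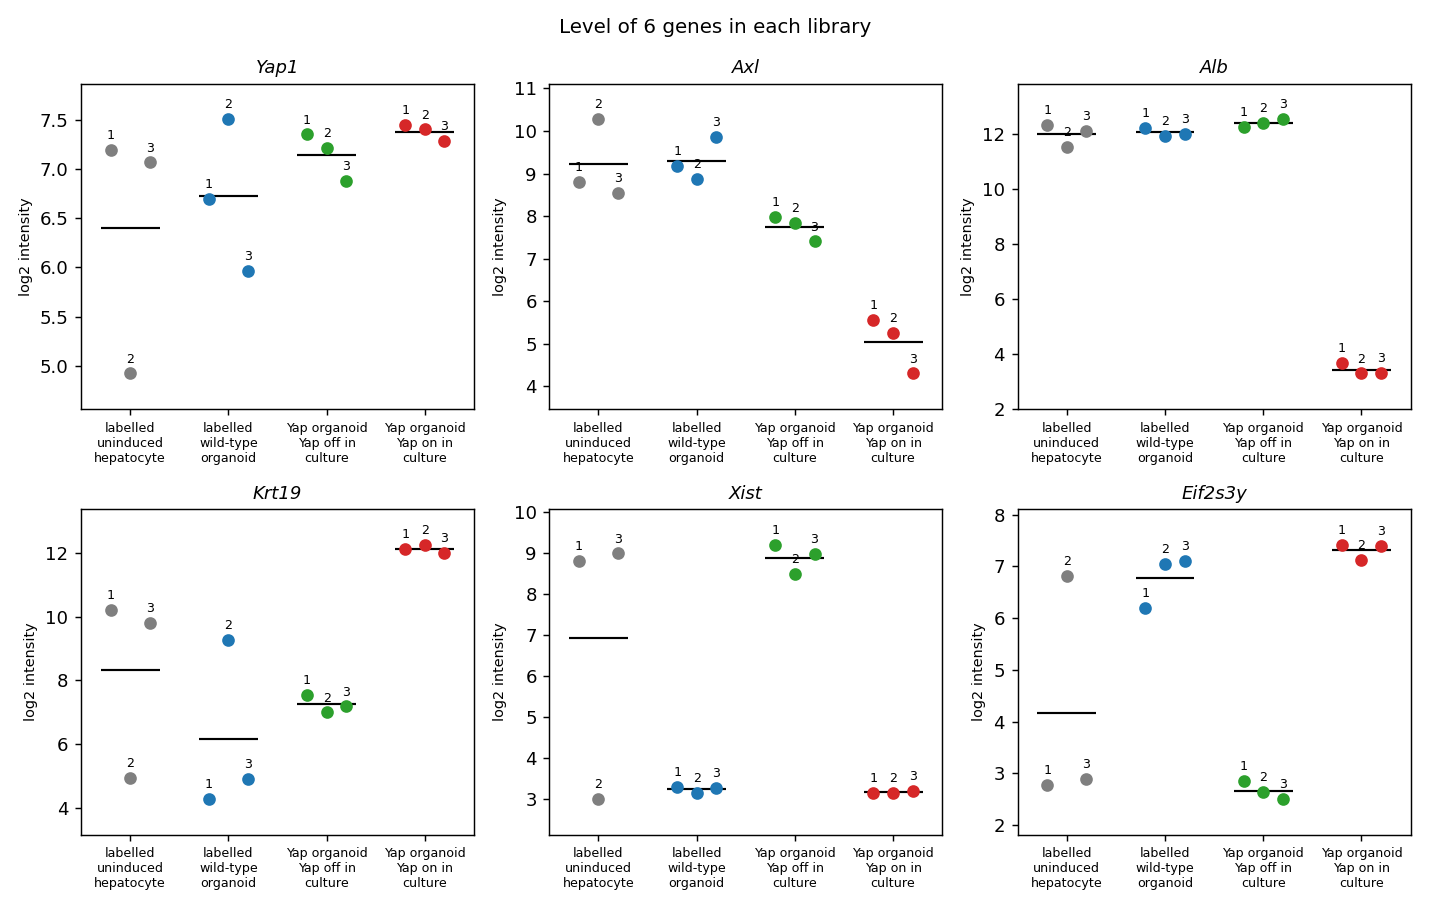
Log2 intensity (vertical axis) of Yap1, Axl, Alb, Krt19, Xist and Eif2s3y in each library, by labelled group (horizontal axis); points carry the replicate number and lines mark group means. Yap1 lies between 7.28 and 7.45 in the Yap-on and between 6.88 and 7.35 in the Yap-off organoids, whereas Xist and Eif2s3y separate these groups in opposite directions.

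The Yap-on and Yap-off organoids also differed in sex-linked genes. Xist, expressed from the inactive X chromosome of females, was at 9.20, 8.49 and 8.98 in the Yap-off and at 3.14, 3.15 and 3.20 in the Yap-on libraries. The Y-linked genes Eif2s3y, Uty and Kdm5d rose by 4.65, 3.36 and 3.21 with Yap on, while Usp9y and Zfy1 differed by -0.09 and -0.08 and did not pass. Every difference between these organoid groups, the liver, biliary and glycolysis genes included, therefore ran along with a difference in sex-linked expression. Without genes on the X and Y chromosomes 2220 genes were called.

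In the fit on all 12 arrays further pathways changed in single members. Wnt targets Lgr5 (1.08), Axin2 (0.98) and Ephb3 (0.75) rose among 16 measured (3 rose and 1 fell adjusted over the list alone; median 0.15, adjusted p = 0.65). In the NRF2 list 4 of 17 rose and 1 fell, also adjusted over the list alone, with the antioxidant enzyme Gpx2 at 5.55, a median of 0.06 and a mean of 0.61 (adjusted p = 0.16). In the TGF-beta list the integrin chain Itgb6 rose by 5.58 and the inhibitor Bambi fell by 2.89, and of 19 members 2 rose and 2 fell, also adjusted over the list alone (median -0.26, mean 0.16, test downward, adjusted p = 1.00). Of 22 Notch genes the ligand Jag2 rose (2.20), over all genes and adjusted over the list alone (median -0.15, mean 0.06, test downward, adjusted p = 0.97). In the inflammatory list Saa3 and Cxcl1 fell, by 4.79 and 3.23, and no other of its 22 members passed, also adjusted over the list alone (median -0.09, adjusted p = 0.64). Of 19 interferon response genes Ifit2 fell by 1.46, as it did adjusted over the list alone (median -0.05, mean 0.09, test upward, adjusted p = 0.97). Of 16 p53 targets 2 rose and 1 fell, also adjusted over the list alone, with Eda2r at 2.53 (median 0.78, adjusted p = 0.16). The p53 list was called higher on the 6 arrays, where 8 members rose and 1 fell (adjusted p = 0.0036; adjusted p = 0.43 with an estimated correlation), and without the 2 doubtful libraries (adjusted p = 0.0088; adjusted p = 0.34 with an estimated correlation).

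Markers of endothelium, macrophages, lymphocytes and neutrophils, and red cells had list medians from 3.05 to 3.74 in all Yap-on and Yap-off libraries, close to that of the hepatocyte markers in the Yap-on organoids (3.59 to 3.67), which left little room for a fall. No member passed, over all genes or adjusted over the list alone, among endothelial (19 measured, median -0.16, adjusted p = 0.88), macrophage (20, -0.44, 0.76), lymphocyte and neutrophil (21, -0.28, 0.88) and red cell markers (5, -0.15, 0.50). In the fit on 6 arrays the macrophage list was called lower with Yap on (adjusted p = 0.0016; adjusted p = 0.43 with an estimated correlation), with 6 members falling and 1 rising. The lymphocyte and neutrophil list was called lower there too, with 7 members falling and 1 rising (adjusted p = 0.016; adjusted p = 0.41 with an estimated correlation), but not without the 2 doubtful libraries (adjusted p = 0.0525). Of 21 stellate cell and fibroblast markers 2 fell, also adjusted over the list alone, among them Reln (-4.34), and the list passed (median -0.28, adjusted p = 0.015; adjusted p = 0.81 with an estimated correlation). Of 12 pancreas markers 3 fell and Pdx1 rose, also adjusted over the list alone (median -0.32, adjusted p = 0.030; adjusted p = 0.63 with an estimated correlation). That call ended in the fit on 6 arrays (adjusted p = 0.0537), under renewed quantile normalization (0.0665) and without genes of low intensity (0.13). It also ended without the library labelled Yap-off 2 (0.0564) or Yap-on 3 (0.0502), and without both doubtful libraries (0.0575). Ribosomal protein genes had a median of 0.30 with no member passing in either count (17 measured, adjusted p = 0.0052; adjusted p = 0.69 with an estimated correlation). This call ended when rows of a gene were averaged (0.11), when the most variable row was taken (0.37) and without genes of low intensity (0.13). No member passed in either count for cholesterol synthesis (19, median 0.32, adjusted p = 0.76) and fatty acid oxidation (18, -0.26, 0.39). Of 19 immediate early genes Egr1 fell by 1.78, over all genes and adjusted over the list alone (median -0.31, adjusted p = 0.67).

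In the fit on 6 arrays more members of most lists were called. Of the glycolysis list 19 of 21 rose and none fell, and 18 rose without the 2 doubtful libraries. Of 24 biliary markers 19 rose and 1 fell, and of 22 drug metabolism genes 18 fell and 2 rose. Basement membrane and adhesion genes rose for 11 and fell for 2 of 20 members, ribosomal protein genes rose for 9 of 17, and fetal liver markers fell for 11 and rose for 3 of 17. Among pathways, NRF2 targets had 8 members higher and 3 lower, TGF-beta 6 and 4, Wnt 6 and 4, interferon response 4 and 2, inflammatory genes 4 and 7, Notch 3 and 4, and immediate early genes 5 and 5. Cholesterol synthesis had 6 higher and 2 lower, fatty acid synthesis 2 and 8, fatty acid oxidation 1 and 5, gastrointestinal markers 6 and 2, stellate cell markers 1 and 6, and endothelial markers 2 and 4. Of these, the lists of NRF2, TGF-beta, Wnt, interferon, inflammatory, Notch, immediate early, cholesterol, fatty acid oxidation, gastrointestinal and endothelial genes were not called on the 6 arrays either.

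The test behind these counts was limma over all 12 arrays, with Benjamini-Hochberg adjustment over 19937 genes. At an unadjusted p under 0.05 there were 5424 genes, and 10665 genes (53.5%) had no overlap between the groups, against 10% expected by chance. The spread of the libraries labelled hepatocyte and wild-type organoid entered the fit: on the 6 arrays alone 6212 genes were called, 2282 of the 2283 among them. Without the 2 doubtful libraries 5914 were called, all 2283 among them and in the same direction. The count was 1449 and 1371 without the library labelled Yap-off 2 or 3, and 1171, 1321 and 1393 without that labelled Yap-on 1, 2 or 3.

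The comparison of Yap-on organoids with the libraries labelled wild-type organoid asks how organoids with Yap kept on differ from organoids that never had the transgene induced. Alb differed by -8.63 (SE 0.20, adjusted p = 8.9e-09) and Serpina1c, an alpha-1-antitrypsin, by -8.46 (SE 0.25), whereas S100a14 rose by 7.65 (SE 0.12) and Prap1 by 7.22 (SE 0.22), with n = 3 libraries per group. limma called 1091 genes, 801 higher and 290 lower in the Yap-on organoids. The libraries labelled wild-type organoid held opposite profiles, as given above, so each list value mixes them.

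Among the 10 largest increases without overlap were also Mmp7 (7.06), Tmem54 (7.03), Ctse (6.91), Adgrg7 (6.86), Rbp2 (6.56), Aspa (6.27), Tmprss2 (6.21) and Msln (6.18). Rbp2 carries retinol in the intestine and Msln is mesothelin. The call for Msln was lost without the library labelled wild-type organoid 1 (adjusted p = 0.0645) or 3 (0.0677) and without that labelled Yap-on 1 (0.0655), 2 (0.0592) or 3 (0.0552). The 10 largest decreases further held Trf (-8.15), Ahsg (-7.57), Fga (-7.53), Fgb (-7.53), Hp (-7.48), Fgg (-7.27), Sparc (-6.98) and Pzp (-6.95). Most are plasma proteins, and Sparc is a matrix protein.

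Of 29 hepatocyte markers 11 fell (19 adjusted over the list alone; median -2.69, adjusted p = 5e-17; adjusted p = 0.0632 with an estimated correlation), and of 29 complement and coagulation genes 9 fell (22 adjusted over the list alone; median -2.76, adjusted p = 8.9e-22; adjusted p = 0.0632 with an estimated correlation). Of 24 biliary markers 11 rose (12 adjusted over the list alone; median 4.18, adjusted p = 8.8e-12; adjusted p = 0.22 with an estimated correlation), with Krt19 at 5.97 (adjusted p = 0.048) and Prom1 at 5.87. Of 20 basement membrane and adhesion genes 6 rose (7 rose and 1 fell adjusted over the list alone; median 2.24, adjusted p = 0.00014; adjusted p = 0.48 with an estimated correlation), Itga2 by 3.78 and Lamb3 by 3.72. No macrophage marker passed in either count, but the list of 20 was lower (median -4.81, adjusted p = 1.8e-06; adjusted p = 0.49 with an estimated correlation), Lyz2 differing by -7.06 (SE 1.82, adjusted p = 0.0551). Of 22 YAP/TEAD targets Axl fell by 4.26, over all genes and adjusted over the list alone (median 0.52, adjusted p = 0.72). Without the 2 doubtful libraries that list was called higher (median 0.75, adjusted p = 0.013; adjusted p = 0.20 with an estimated correlation). The libraries labelled wild-type organoid 1 and 3, left in that fit, had high Cyp2e1 and macrophage transcripts. The glycolysis list was called higher (median 1.35, adjusted p = 1.4e-05; adjusted p = 0.48 with an estimated correlation). In it 1 of 21 members rose, Car9 by 5.25 (3 rose adjusted over the list alone).

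In this comparison 19 of the 32 lists were called, and 0 of them held with an estimated correlation on all 12 arrays. The biliary and the lymphocyte and neutrophil lists did without the 2 doubtful libraries (both adjusted p = 0.0036). At an unadjusted p under 0.05 there were 4400 genes, and 26.0% of genes had no overlap, against 10% by chance. The count rose to 6022 without the library labelled wild-type organoid 2 and fell to 706, 675, 575, 639 and 694 without that labelled wild-type organoid 1, wild-type organoid 3, Yap-on 1, Yap-on 2 and Yap-on 3. The 6 arrays alone gave 699 genes, 604 of them among the 1091, and omitting both doubtful libraries gave 8167, all 1091 among them. In simulated groups with the spread of these arrays and few changed genes, 41.6% of calls in this comparison were false. That simulation called 233 genes against 1091 in the data, so its false share does not carry over to these calls.

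The comparison of Yap-off organoids with the libraries labelled wild-type organoid asks what remained 2 weeks after Yap was turned off. Cyp2b10, a xenobiotic-induced cytochrome P450, rose by 5.95 (SE 0.25, adjusted p = 3.5e-06), the estrogen sulfotransferase Sult1e1 by 6.57 (SE 0.16, adjusted p = 6e-08), Tff3, a mucosal trefoil peptide, by 6.71 (SE 0.62, adjusted p = 0.0012) and Mt4, a metallothionein, by 6.60 (SE 0.34, adjusted p = 1.8e-05), with n = 3 libraries per group. limma called 520 genes, 283 higher and 237 lower. After renewed quantile normalization the split was 399 and 201. Sex-linked expression ran along with this comparison too: Eif2s3y, Uty and Kdm5d fell by 4.12, 3.33 and 2.45 in the Yap-off organoids, and Xist, higher by 5.66, narrowly missed the threshold (adjusted p = 0.0502), so a difference in sex cannot be separated from what remained after Yap.

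The 10 largest increases also held Spink1 (6.44), Igfbp1 (5.86), Igf2 (5.45), Serpina3n (4.67), Sult1d1 (4.63) and Rdh9 (4.61), and the 10 largest decreases Dab2 (-4.08), Id3 (-3.37), Arrb1 (-3.24), Prex2 (-3.12), Meis2 (-3.08), Tmem140 (-2.99), Cyp4a12a (-2.94), Clec2d (-2.90), Ms4a4b (-2.79) and Anxa1 (-2.74). Dab2, Clec2d and Ms4a4b are known from macrophages, endothelium or lymphocytes. Of the 20 genes, 7 kept their call in every fit without 1 library: Tff3, Mt4, Sult1e1, Cyp2b10, Sult1d1, Rdh9 and Anxa1. In the fit on 6 arrays 8 of the 20 kept it.

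Of 29 complement and coagulation genes 13 rose (17 rose and 1 fell adjusted over the list alone; median 2.05, adjusted p = 1.5e-10; adjusted p = 0.27 with an estimated correlation), F9 by 4.07 and F12 by 3.89. Of 29 hepatocyte markers 3 rose (15 rose and 1 fell adjusted over the list alone; median 1.46, adjusted p = 5.6e-07; adjusted p = 0.27 with an estimated correlation), Itih3 by 4.59 and the liver regulator Foxa3 by 3.62. The fetal liver list had 3 of 17 members higher (5 adjusted over the list alone; median 1.60, adjusted p = 0.00030; adjusted p = 0.30 with an estimated correlation). Cholesterol synthesis was higher with 1 of 19 members called, Dhcr7 at 2.11 (3 adjusted over the list alone; median 1.28, adjusted p = 4.5e-06; adjusted p = 0.44 with an estimated correlation). Markers of blood and vessel cells were lower as lists, with no member called in either count: macrophage (median -4.29, adjusted p = 5.6e-07), endothelial (-3.76, 5.8e-08) and lymphocyte and neutrophil markers (-2.07, 2.4e-07), with adjusted p = 0.48, 0.44 and 0.44 with an estimated correlation. Of 19 interferon response genes 2 fell (3 adjusted over the list alone; median -1.89, adjusted p = 2.5e-08; adjusted p = 0.43 with an estimated correlation). The YAP/TEAD list did not pass and no member did in either count, with its median of 0.30 and mean of 0.65 above and its test below 0 (adjusted p = 0.94). Without the 2 doubtful libraries it was called higher (median 1.15, adjusted p = 0.014; adjusted p = 0.29 with an estimated correlation). That fit compares with the libraries labelled wild-type organoid 1 and 3, which had high Cyp2e1 and macrophage transcripts.

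In this comparison 16 of the 32 lists were called, and 0 of them held with an estimated correlation on all 12 arrays. The biliary (adjusted p = 0.025) and the lymphocyte and neutrophil lists (0.0031) did without the 2 doubtful libraries. At an unadjusted p under 0.05 there were 3804 genes, and 19.3% of genes had no overlap, against 10% by chance. The count was 3864 without the library labelled wild-type organoid 2, 234 and 163 without that labelled wild-type organoid 1 or 3, and 101 and 107 without that labelled Yap-off 2 or 3. On the 6 arrays alone 61 genes were called, 53 of them among the 520, and without both doubtful libraries 6449, all 520 among them. On simulated groups with the spread of these arrays and few changed genes, 53.6% of calls in this comparison were false. That share does not carry over to the calls in the data, but their count is read with caution.

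The comparison of the libraries labelled wild-type organoid with those labelled hepatocyte asks how culture as organoids changes liver cells. Labels and profiles conflicted in these groups, and few genes followed the labels. limma called 10 genes, 5 higher and 5 lower in the libraries labelled wild-type organoid. Hk2, a hexokinase of glycolysis, fell by 1.78 (SE 0.24, adjusted p = 0.047), the scavenger receptor Colec12 by 2.32 (SE 0.23, adjusted p = 0.012), Guca1a, a guanylate cyclase activator, by 2.02 (SE 0.23, adjusted p = 0.021), Ddit4, a stress-induced inhibitor of mTOR, by 2.61, and Gde1 by 1.49. Cyb561a3, a cytochrome b561, rose by 1.42 (SE 0.14, adjusted p = 0.012), as did Psd3 (1.31), Trmt1l (1.13), 2310067E19Rik (1.65) and 4930503L19Rik (2.05), with n = 3 libraries per group. Ddit4, Gde1, Psd3, Trmt1l and the last 2 fall outside the rule for named genes and are given because they complete the count.

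The immediate early and dissociation list was lower in the libraries labelled wild-type organoid (median -1.05, adjusted p = 1e-08), on all 12 arrays the only 1 of 10 list calls that held with an estimated correlation (adjusted p = 0.022). It did not without the 2 doubtful libraries (0.24), whereas the lymphocyte and neutrophil list did there (0.0030). None of its 19 members passed over all genes, and 8 fell when adjusted over the list alone. Fos and Atf3 differed by -1.85 and -2.26, neither passing over all genes. Of 21 glycolysis genes 1 fell (7 adjusted over the list alone; median -1.28, adjusted p = 9.6e-10; adjusted p = 0.70 with an estimated correlation). The endothelial list was higher (median 2.27, adjusted p = 1.4e-07; adjusted p = 0.70 with an estimated correlation) with no member called in either count. Hepatocyte markers (median -0.04, mean 0.04, test upward, adjusted p = 0.91) and biliary markers (median -0.12, adjusted p = 0.91) did not pass, nor did any of their members in either count.

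At an unadjusted p under 0.05 there were 1762 genes, and 7.64% of genes had no overlap, against 10% by chance. The count was 870 without the library labelled hepatocyte 2 and 1604 without that labelled wild-type organoid 2, against 0, 2 and 18 without that labelled hepatocyte 1, hepatocyte 3 and wild-type organoid 3. None of Cyb561a3, Guca1a, Hk2 and Colec12 kept its call throughout these fits and the fit on 6 arrays, in which limma called 0 genes. In simulated groups with this spread and few changed genes 65.8% of calls were false. That simulation called 474 genes against 10 in the data, so its false share does not carry over to these calls. Without both doubtful libraries 6117 genes were called, all 10 among them. The libraries left in that fit differed in sex-linked expression. Those labelled wild-type organoid 1 and 3 had Y-linked expression and those labelled hepatocyte 1 and 3 had none. A difference in sex therefore cannot be separated from culture there. Leaving out the libraries that differed from the rest of their groups also lowers the spread. In the fit without both doubtful libraries the YAP/TEAD list was lower in the libraries labelled wild-type organoid (median -1.76, adjusted p = 0.00041; adjusted p = 0.12 with an estimated correlation) and the macrophage list higher (median 6.03, adjusted p = 9.6e-23; adjusted p = 0.11 with an estimated correlation).

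Against the libraries labelled hepatocyte, limma called 378 genes in the Yap-off organoids, 175 higher and 203 lower, and 1234 in the Yap-on organoids, 850 higher and 384 lower. Which direction prevailed in the Yap-off organoids depended on the fit: higher genes outnumbered lower ones after renewed quantile normalization (159 and 140), with an intensity trend (152 and 81), on the 6 arrays (96 and 47), with a 2-fold minimum (164 and 136) and at adjusted p under 0.01 (52 and 32). They also did so without the library labelled hepatocyte 1 (68 and 58), hepatocyte 3 (91 and 67), Yap-off 1 (147 and 133), Yap-off 2 (96 and 70) or Yap-off 3 (64 and 49). Lower genes stayed in the majority after centring on the median (152 and 199), with either other choice of row (178 and 190, 176 and 195), without genes of low intensity (175 and 176), with array weights (949 and 1477), without the library labelled hepatocyte 2 (271 and 566) and without both doubtful libraries (1042 and 1750). Cyb561a3 was higher in both, by 1.06 (SE 0.14) and 1.34 (SE 0.14), and Guca1a (-2.04 and -1.78), Hk2 (-2.25 and -1.62) and Colec12 (-1.55 and -3.35) were lower, n = 3 libraries per group. In the Yap-off organoids the call for Colec12 ended without the library labelled hepatocyte 1 (adjusted p = 0.0503) or Yap-off 3 (0.058), and that for Cyb561a3 in the fit on 6 arrays (0.0659). In the Yap-off organoids 8 of 29 complement and coagulation genes rose (16 adjusted over the list alone; median 1.84, adjusted p = 4.5e-16; adjusted p = 0.0821 with an estimated correlation), Serpind1 by 3.56 and F9 by 3.91. Of 29 hepatocyte markers 3 rose there (10 adjusted over the list alone; median 1.17, adjusted p = 3.4e-10; adjusted p = 0.0821 with an estimated correlation). Glycolysis genes were lower, 5 of 21 falling (7 adjusted over the list alone; median -1.21, adjusted p = 3.4e-10; adjusted p = 0.21 with an estimated correlation), with the lactate carrier Slc16a3 at -2.35. In the Yap-on organoids 15 of 29 complement and coagulation genes fell (18 adjusted over the list alone; median -2.48, adjusted p = 2.4e-19; adjusted p = 0.0877 with an estimated correlation), as did 12 of 29 hepatocyte markers (14 adjusted over the list alone; median -2.42, adjusted p = 3.2e-14; adjusted p = 0.0877 with an estimated correlation). Of 24 biliary markers 10 rose (11 adjusted over the list alone; median 3.07, adjusted p = 1.9e-12; adjusted p = 0.18 with an estimated correlation), Ehf, an epithelial ETS factor, by 6.34 and Muc1 by 5.94. The macrophage list was lower in the Yap-off (median -2.48, adjusted p = 0.00043; adjusted p = 0.70 with an estimated correlation) and Yap-on organoids (median -3.21, adjusted p = 0.0019; adjusted p = 0.74 with an estimated correlation). Both calls ended without the library labelled hepatocyte 2 (adjusted p = 0.72 and 0.43), and no member passed in either count.

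At an unadjusted p under 0.05 there were 2588 genes for the Yap-off and 3905 for the Yap-on organoids against the libraries labelled hepatocyte, and 19.6% and 39.6% of genes had no overlap, against 10% by chance. Of 18 lists called for the Yap-off and 15 for the Yap-on organoids, 0 held with an estimated correlation on all 12 arrays. Without the 2 doubtful libraries the fatty acid oxidation, bile acid, drug metabolism and glycolysis lists held for the Yap-off organoids (adjusted p from 0.040 to 0.041) and the biliary list for the Yap-on organoids (0.0072). The Yap-off count was 837 without the library labelled hepatocyte 2, 126 and 158 without that labelled hepatocyte 1 or 3, and 166 and 113 without that labelled Yap-off 2 or 3. On the 6 arrays alone it was 143, of which 103 were among the 378. The Yap-on count was 1935 without the library labelled hepatocyte 2 and 732, 764 and 815 without that labelled Yap-on 1, 2 or 3. Without both doubtful libraries the counts were 2792, with all 378 among them, and 4300, with 1232 of the 1234. In the latter fit the Yap-on organoids had Y-linked expression and the libraries labelled hepatocyte 1 and 3 had none. A difference in sex therefore cannot be separated from Yap there. With all 12 arrays only hepatocyte 2 of the libraries labelled hepatocyte had Y-linked expression. In simulated groups with few changed genes 26.9% of calls for the Yap-off and 29.8% for the Yap-on organoids were false. Those simulations called 186 and 191 genes against 378 and 1234 in the data, so these shares do not carry over either.

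All 3 comparisons against the libraries labelled hepatocyte shared 5 calls in the same direction, 2 higher and 3 lower, where independent lists of these sizes would share 0.0019 and 0.00098. Both comparisons against the libraries labelled wild-type organoid shared 65, 33 higher and 32 lower, against 11.4 and 3.45. In 20 simulations with unchanged groups and the same controls 0 calls were shared in either set, but unchanged groups leave next to nothing to share, so this does not measure what shared controls add between lists of these sizes. Part of the excess may come from the shared controls. Without both doubtful libraries the shared calls numbered 688 and 4492. The genes that separated the labelled wild-type organoid and hepatocyte libraries were followed in the comparison of Yap-on with Yap-off organoids. The arrays of that comparison entered the spread by which those genes were called, and 0 were called by limma without them (1762 genes at an unadjusted p under 0.05 with them). With 5 genes each way, the hepatocyte-high genes had a median of 0.26 and the organoid-high genes of 0.28, and neither set passed (adjusted p = 0.33 for both). Without the 2 doubtful libraries 200 organoid-high genes had a median of -0.23 (adjusted p = 0.0055) and 200 hepatocyte-high genes of 0.20 (adjusted p = 0.76). The sets of 200 genes were tested with the preset correlation only, not with an estimated one. Those genes came from a contrast in which the libraries labelled wild-type organoid had macrophage markers higher by a median of 6.03 and endothelial markers by 5.37, so they also carry a difference in blood and vessel cells. That contrast ran along with Y-linked expression too, as does the comparison of Yap-on with Yap-off organoids, and sex-linked genes were not left out of the sets.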

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

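The fit without the libraries labelled hepatocyte 2 and wild-type organoid 2, and the count without X- and Y-linked genes, were chosen after seeing the data, and all other alternatives before. No called list or named gene changed direction under any alternative. The direction of all other calls was compared only with the fit without both doubtful libraries, where genes called in both fits kept it. Renewed quantile normalization, centring on the median, the choice of row, the filter on low values and the 2-fold minimum left every count within 1.5 times its value. In the order Yap-on against Yap-off organoids, Yap-off and Yap-on against wild-type organoids, wild-type organoids against hepatocytes, and Yap-off and Yap-on against hepatocytes, array weights gave 7688, 5199, 8293, 5431, 2426 and 6334 called genes. Adjusted p under 0.01 gave 1027, 69, 544, 0, 84 and 666, as a stricter threshold must give fewer. Leaving out 1 library at a time gave 1171 to 2169, 101 to 3864, 575 to 6022, 0 to 1604, 113 to 837 and 732 to 1935. Only the 6 arrays compared gave 6212, 61, 699, 0 and 143 for the comparisons before the last. An intensity trend with robust eBayes gave 324, 2 and 233 for Yap-off against wild-type organoids, wild-type organoids against hepatocytes and Yap-off organoids against hepatocytes. Without both doubtful libraries the 6 counts were 5914, 6449, 8167, 6117, 2792 and 4300, the organoid-high genes had a median of -0.23 in Yap-on against Yap-off organoids, and the overlaps held 688 genes in the 3 comparisons against hepatocytes and 4492 in the 2 against wild-type organoids. Except for the stricter threshold, the cause was not tested. The array weights were lowest for the libraries labelled hepatocyte 2 (0.166) and wild-type organoid 2 (0.121), with the next lowest at 0.490. The fit with array weights is therefore not separate from leaving out both doubtful libraries. The alternatives with 50 and 500 hepatocyte-high and organoid-high genes were not run, since only 5 genes each way were called. Of 14 lists called in Yap-on against Yap-off organoids, 2 held with an estimated correlation on all 12 arrays and 11 with each of the 6 libraries compared left out in turn. Here and below only libraries of the groups compared were left out singly. With each library left out, 11 of 16 held in Yap-off and 16 of 19 in Yap-on against wild-type organoids. Against hepatocytes 5 of 10 held for wild-type, 11 of 18 for Yap-off and 10 of 15 for Yap-on organoids. Of the 20 genes named in Yap-on against Yap-off organoids 19 held with each library left out, against 7 of 20 in Yap-off against wild-type organoids. Values near background, where genes that are off lie, limit the size of decreases to that level and of increases from it.

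With the replicate number as a replicate block, the counts were 170 for Yap-off against wild-type organoids, 0 for wild-type organoids against hepatocytes and 167 for Yap-off organoids against hepatocytes (93 higher and 74 lower), and the cause was not tested. Deviations from the group mean correlated at -0.51, -0.71 and -0.66 between hepatocyte and wild-type organoid libraries of the same number. These values cannot tell whether the numbers pair. The number 2 libraries departed from their groups in opposite directions (macrophage list 6.85 and -7.09), which sets the sign at every number. Elsewhere the correlations lay between -0.14 and 0.12, without a sign of pairing.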

Other observations

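The split counts were planned before the data were seen, and every other test below was chosen after the result it concerns had been seen. The genes in this and the next paragraph were chosen after their values were seen. A set of genes was high in the Yap-off organoids only. Sult1e1 averaged 9.08 ± 0.29 (log2, SD) there and 2.28 ± 0.09 in the Yap-on organoids, and Mt4 10.29 ± 0.46 and 3.82 ± 0.08. The retinol dehydrogenase Rdh9 and the matrix protein Reln followed the same course, with differences of -4.11 and -4.34 in Yap-on against Yap-off organoids and adjusted p of 5.9e-06 and 1.5e-06. None of these 4 genes was called in Yap-on organoids against the libraries labelled wild-type organoid.

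Other genes were high in both groups in which Yap had been on in the liver. Krt23, a keratin of injured liver and ducts, stood at 6.62 ± 0.23 in the Yap-off and 7.24 ± 0.29 in the Yap-on organoids, against 3.95 ± 0.57 and 3.66 ± 0.47 in the libraries labelled hepatocyte and wild-type organoid. Tff3 followed, at 12.21 ± 0.22 and 9.04 ± 1.34 against 5.45 ± 0.79 and 5.50 ± 0.56.

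The libraries labelled hepatocyte and wild-type organoid did not group by label. An exchange of labels between the groups stays open: setting each number 2 library with the other group's number 1 and 3 called 5317 genes, against 10 for the labels as given, but that split was chosen from the grouping already seen and would call many genes whatever its cause, and Y-linked expression set hepatocyte 2 with wild-type organoid 1 and 3 but kept wild-type organoid 2 apart from hepatocyte 1 and 3, which had none. An exchange of the number 2 libraries alone was argued against, since the libraries labelled hepatocyte 1 and 3 held fewer hepatocyte relative to biliary transcripts than those labelled wild-type organoid 1 and 3 (-1.30, pairs from -1.22 to -1.58). Immune and endothelial cells mixed into the library labelled hepatocyte 2 were argued against only as its sole difference from hepatocyte 1 and 3. Mixing alone would dilute both lists alike, whereas its YAP/TEAD list lay lower than its hepatocyte list relative to them (-1.86, and -1.61 against hepatocyte 1 alone). As hepatocyte 1 and 3 themselves had high Krt19 and Ankrd1, this does not exclude such cells. The macrophage and endothelial lists of hepatocyte 2 lay 6.85 and 3.35 higher than in hepatocyte 1 and 3, so mixing beside another difference stays open. No biological explanation was tested.

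Hepatocyte genes were lower in Yap-on than in Yap-off organoids (-4.20). Sex of the animals as the whole cause was argued against: in the other 4 libraries with Y-linked expression the median over the list's genes of the difference from the Yap-on mean was at least 0.81, and the same measure ranged by at most 0.36 within a Yap organoid group (list median level at least 5.99, against at most 3.67 in the Yap-on organoids). Against the Yap-off organoids these libraries lay at -1.36, -1.02, -2.33 and -1.20, and those labelled hepatocyte 1 and 3, without Y-linked expression, at -0.97 and -1.06, so sex as part of the cause stays open. Under the renewed scaling that left the list smallest, it stayed at -4.16. The deposited values were already quantile normalized, with array medians of 4.16 to 4.28 in the Yap-off and 4.17 in the Yap-on organoids. Renewed scaling thus had little to change, and this test cannot decide on scaling of the arrays. Loss of hepatocyte identity under continued Yap is the explanation the design offers, and as sex and doxycycline changed together in this comparison it remains untested. The libraries labelled wild-type organoid had Y-linked expression like the Yap-on organoids. By the same measure their hepatocyte list lay above the Yap-on mean by 4.16, 0.81 and 3.74 in numbers 1, 2 and 3. Their labels and profiles conflicted, so this comparison does not settle the explanation either.

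Few YAP/TEAD genes were called between Yap-on and Yap-off organoids, and the list was not called as a whole. The spread of the libraries labelled hepatocyte and wild-type organoid is a candidate explanation for the few calls, since 14 of 22 members were called on the arrays of this comparison alone, against 2 on all 12 (6212 against 2283 over all genes). As 7 of the 14 rose and 7 fell, the list test on those arrays (adjusted p = 0.87) decides nothing about what a shift would need. A transgene that the Yap1 probe set does not see stays open, as Yap1 differed by 0.23. Feedback within the Hippo pathway was not tested.

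Each comparison was set against the 10 splits of its 6 arrays, too few for a share under 0.05. Where groups differ, a split that mixes them also puts their difference into the spread. Low counts for the other splits were thus largely fixed in advance, and the contrast with them decides nothing about the labels. The labels called the most genes in 5 comparisons, where 1 split reached the count: 2283 against at most 0 in Yap-on and Yap-off organoids, 520 against 3 and 1091 against 0 in Yap-off and Yap-on against wild-type organoids, and 378 and 1234 against 0 in Yap-off and Yap-on against hepatocytes. In wild-type organoids against hepatocytes 2 splits reached the 10 genes of the labels, and the one calling 5317 points to a structure of the samples other than the labels.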
